A study of Mus musculus with 11 samples.

How the data were processed

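RNA from 11 sorted T cell samples, 6 WT and 5 Il23r knockout, was amplified, labelled with biotin and hybridised to a mouse Illumina bead array with 1 colour, per the labels. The non-normalized table holds the intensity of each probe on a linear scale, deposited by the authors and read out with GenomeStudio 1.6.0, per the submitters' processing notes. No background subtraction or normalization is visible in these values, and other steps are not given in the sources used here. Beside each intensity the authors deposited a detection score between 0 and 1. Its header calls it a detection p, but the score rose with the intensity on every array (Spearman correlation across probes of at least 0.984) and was 1 for bright probes, so it was read as 1 minus the detection p. The series value table deposited by the authors holds log2 values, which were found by comparison to be log2 of the same intensity minus the 75th percentile of each array. Scale and centring were thereby settled, and these values have no direction since each array has 1 sample.

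The rows of the intensity table carry bead numbers, and they were joined to probe names through the match of all 11 values per row with the series value table, where the largest difference was 0.000339 log2. Gene names came from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and were left unnamed, and 10378 were not listed. Of the genes in the fixed lists, 41 had no probe under that name or a synonym and were not analysed here. Gene order and synonyms came from a RefSeq table of assembly GRCm38.p6.

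Background was corrected and arrays were normalized with neqc of limma 3.58.1 in R 4.3.3, which fits normexp with negative controls inferred from the detection p, adds an offset of 16 and applies quantile normalization. The offset shrinks fold changes of dim probes. A probe was kept if its detection p was under 0.05 on at least 5 of the 11 arrays, which left 18003 probes and 9139 named genes. Genotypes were compared by lmFit and eBayes on the log2 scale, two-sided, with genotype as the single term and Benjamini-Hochberg adjustment over all kept probes, and a probe was called at an adjusted p under 0.05. Fold changes are knockout minus WT. Where a probe was not above background on any array of a genotype, the fold is given as a lower bound. It sets the mean of the bright group against the mean, in the dim group, of the higher of the lowest value among probes above background on that array and the probe's own value.

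Before the data were examined, 27 gene lists were fixed, and each gene was represented by its brightest kept probe, so that other probes of a list member can differ. The 23 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. With the preset value 8 lists passed, and with the estimated value 0 passed. The rule for named genes was also fixed then. It took Il23r, up to 12 genes in each direction with the largest fold change among those called (the probe with the smallest p), up to 4 members of each list with the smallest p, the 3 most abundant members of each list of markers of other cell types, and, of a fixed set of signature genes, those analysed here: Il17a, Il17f, Il22, Ifng, Csf2, Il10, Tbx21, Foxp3 and Gata3. Genes named beyond it were chosen after their values were seen: Rora, Batf, Irf4, Stat3, Tmem176a and Il10rb in the results, as further members of fixed lists, and the 14 genes that open the other observations.

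The same code was tested on simulated data made from the spread of these arrays for this comparison, over 18003 probes. With 50 probes changed at each size, it recovered 50%, 98%, 100% and 100% of probes at log2 changes of 0.5, 1, 1.5 and 2, and 7 of 181 calls were false. A list shifted by 0.5 was recovered, with 1 other list called at the preset correlation and 0 at the estimated one. The noise was drawn for each probe on its own, without correlation between genes. In the data the estimated correlation reached 0.64 in the cell cycle list and 0.71 in the myeloid list. The simulation therefore does not show how often lists of correlated genes are called falsely.

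Alternatives fixed in advance were the replicate number as a block, no background correction, equal medians in place of quantile normalization, the authors' log2 values, no filter or a stricter filter on dim probes, a trended and robust variance model, array weights, other thresholds, another choice of probe per gene, and leaving out each array. Adding array brightness as a covariate, and using replicates 1 to 5 alone, were chosen after seeing the data. Slides are not given in the sources used here, so a slide that held a single genotype could not be told apart from it.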

Results

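Messenger RNA levels were measured with an Illumina bead array in mouse T cells carrying the T cell receptor β chain and CD4, sorted from the lamina propria of the colon, the connective tissue layer beneath the gut epithelium. The cells came from Rag1-deficient mice, which have no mature T or B cells of their own. These mice had developed colitis after receiving WT and Il23r-deficient naive CD4 T cells together, so that both genotypes had lived in the same inflamed recipients. The series holds 6 WT samples and 5 Il23r knockout samples, all on the C57BL/6 background per the labels. Between 17309 and 18440 of the 45281 probes were above background on an array, and the median raw intensity of an array ranged from 107.6 to 176.7. The labels do not say whether the samples of a genotype came from separate recipients, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

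The comparison of knockout with WT cells asks which transcripts of intestinal CD4 T cells depend on the receptor for interleukin 23 (IL-23), a cytokine that sustains T cells producing interleukin 17 (IL-17). The probe for Il23r itself was above background on 0 of the 11 arrays, with a mean log2 value of 4.78 ± 0.11 (SD, n = 6) in WT and 4.71 ± 0.08 (SD, n = 5) in knockout cells. It therefore gives no check of the genotype labels. Il22, a cytokine gene that IL-23 is known to induce, was above background on 2 of the 6 WT arrays and on 0 of the 5 knockout arrays. Its probe was too dim for the main test, and it did not pass without the filter on dim probes (adjusted p = 0.27).

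Knockout cells held far more Il17f transcript than WT cells, and also more Il17a, Ccl20, Gpr15 and Il4. Il17f, which encodes an IL-17 family cytokine, rose from 5.36 ± 0.45 (SD, n = 6) in WT to 9.02 ± 0.24 (SD, n = 5) in knockout cells, a log2 fold change, knockout minus WT, of 3.66 ± 0.20 (SE, adjusted p = 1.45e-07). Its probe was above background on 1 WT array and on all 5 knockout arrays. Il17a, the founding member of that family, rose from 9.27 ± 0.84 to 11.06 ± 0.40, a log2 fold change of 1.79 ± 0.34 (adjusted p = 0.0189). Gpr15, a receptor that guides T cells to the colon, rose by 2.20 ± 0.26 (adjusted p = 0.000562), and its second probe by 1.09 ± 0.17. Ccl20, the chemokine bound by Ccr6, rose by 1.68 ± 0.22 (adjusted p = 0.00149). Il4, the type 2 cytokine, rose by 1.78 ± 0.37 (adjusted p = 0.0306).

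Cdk5rap1, a mitochondrial tRNA-modifying enzyme, rose by 2.25 ± 0.11 on its first probe and by 2.23 ± 0.12 on its second, while another probe was at 0.30 and did not pass. Gprasp2, a sorting protein of G protein-coupled receptors, rose by 2.22 ± 0.24. Camk2b, a subunit of a calcium-dependent kinase, rose by 1.90 ± 0.15. The tested probe of Snurf, an imprinted gene, was not above background on any WT array and was at least 2.82-fold higher in knockout cells (adjusted p = 0.0407), where its values spread widely (7.25 ± 1.38, SD, n = 5). Other Snurf probes were too dim for the main test. Without the filter on dim probes they were at 0.05, 1.03 and 0.04 and did not pass. Fzd10os (1.51), the heparan sulfate sulfotransferase gene Hs3st1 (1.48) and the ribonuclease gene Rnase4 (1.48) completed the 12.

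The deepest loss in knockout cells was that of Erdr1, named as an erythroid differentiation regulator. Its log2 value was 12.81 ± 0.10 (SD, n = 6) in WT and 6.83 ± 0.25 (SD, n = 5) in knockout cells, so that the transcript fell by 5.98 on the log2 scale (SE 0.11, adjusted p = 7.05e-13). Its second probe was not above background on any knockout array and was at least 26.1-fold higher in WT cells. The transcript 1110017D15Rik was likewise undetected on the 5 knockout arrays and at least 10.5-fold higher in WT cells (adjusted p = 6.08e-10). Ide, the insulin-degrading enzyme, had a log2 fold change of -2.72 ± 0.15 on 1 probe (adjusted p = 1.81e-07), but of -0.24 and -0.06 on its other probes, which did not pass.

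Smaller decreases were found for Pkib (-1.86), an inhibitor of protein kinase A, the integrin gene Itga3 (-1.67) and the RNA-binding protein gene Igf2bp3 (-1.64). Of the 5 probes of Igf2bp3, 4 fell and the remaining probe was at 0.13 without passing. The dimmest of the 4 that fell missed the threshold without knockout sample 2, 3, 4 or 5 (adjusted p up to 0.0844). Rell1 (-1.55), the glutathione transferase gene Gstt1 (-1.36), the RNA-binding protein gene Rbm47 (-1.14), the receptor component gene Ramp1 (-1.08) and the metalloproteinase gene Mmp25 (-1.05) also fell. Znhit6 fell by 1.06 on the log2 scale on 1 probe, and its other probe was at 0.22 and did not pass.

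In all, limma called 320 of the 18003 tested probes at a Benjamini-Hochberg adjusted p under 0.05, of which 210 were higher and 110 lower in knockout cells. With the arrays scaled to equal medians in place of quantile normalization, the split was 199 higher and 58 lower, so that the share of higher calls was 77.4% against 65.6%. The called probes named 142 higher and 81 lower genes, with 1 gene in both sets, and 51 called probes had no gene name. At least a 2-fold difference was seen for 61 called probes, 39 of them higher. For 268 of the 320 probes no WT array overlapped with a knockout array, as for 578 of all 18003 tested probes, against 0.433% by chance. The count rested on single arrays: it was 513 without WT sample 2, but 162 without WT sample 3, 159 without WT sample 5, and 187, 178 and 181 without knockout samples 2, 3 and 4. Il17a missed the threshold without knockout sample 2 or 3 (adjusted p up to 0.0523) and in 2 of 10 other settings, among them no detection filter (adjusted p = 0.0544). Il4, Hs3st1 and Snurf missed it in 6 of 11, 6 of 11 and 5 of 6 fits that left out 1 array (adjusted p up to 0.0842, 0.084 and 0.0803). They also missed it in 3 of 10, 3 of 9 and 6 of 9 other settings, among them no detection filter (adjusted p = 0.077, 0.077 and 0.105). With a knockout sample left out, the Snurf probe failed the detection filter. Its dependence on knockout sample 2 (9.58, the others 5.88 to 7.03) was therefore not tested.

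**Figure D1:**
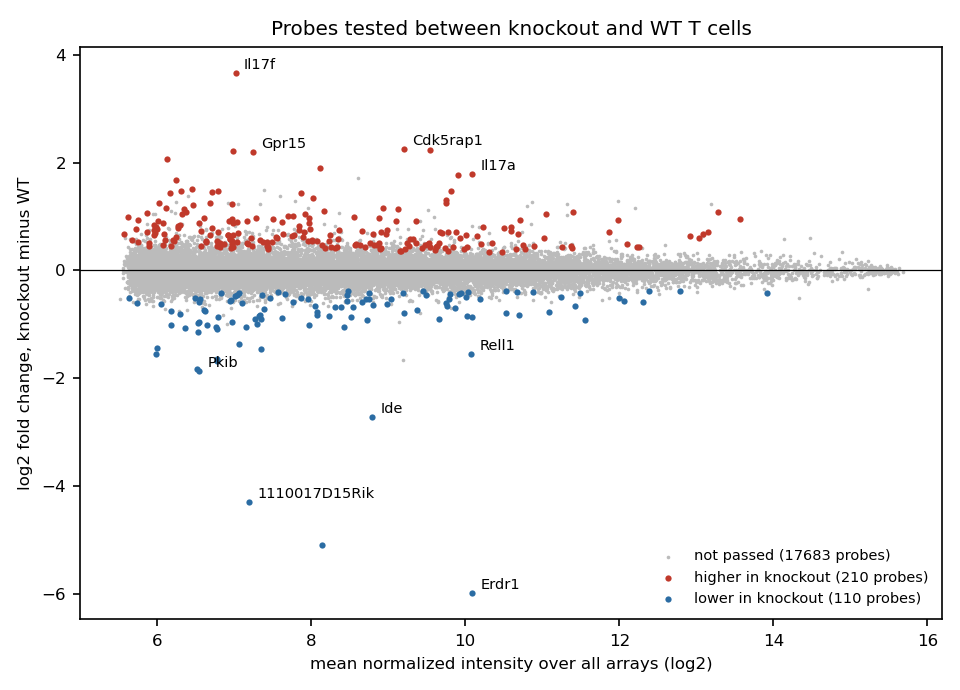
Each point is 1 of the 18003 tested probes, with its mean normalized log2 intensity over all 11 arrays on the x axis and its log2 fold change, knockout minus WT, on the y axis; red and blue points are the 210 higher and 110 lower probes at adjusted p under 0.05, and grey points did not pass. Erdr1 lies lowest, at -5.98, and Il17f highest, at 3.66; values of probes that were not above background in 1 genotype are drawn as computed.

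Of the 16 measured genes of the IL-17 program, 4 rose and 4 fell. Il17f, Il17a, Ccl20 and Ccr6, the chemokine receptor of IL-17-producing T cells (1.13 ± 0.21, adjusted p = 0.0176), rose. Ltb4r1, the leukotriene B4 receptor (-0.90 ± 0.16, adjusted p = 0.0121), Il17re, a receptor subunit for the epithelial cytokine IL-17C (-0.64 ± 0.12), the interleukin 1 receptor gene Il1r1 (-0.71 ± 0.15) and Tmem176a (-0.82 ± 0.18) fell. The genes for the transcription factors Rora (-0.12), Batf (-0.17), Irf4 (-0.33) and Stat3 (-0.03) did not pass. The median of the list was -0.06, its mean was 0.36, and the set test leaned upward (camera adjusted p = 0.755). Adjusted over the list alone, the count was again 4 higher and 4 lower. Ccr6 missed the threshold without knockout sample 3 (adjusted p = 0.053), and Il1r1 without WT sample 1 or knockout sample 1, 2 or 4 (adjusted p up to 0.0748), and Tmem176a in 7 of 11 such fits (adjusted p up to 0.11). With equal medians the calls of Il17re and Il1r1 were lost (adjusted p = 0.0952 and 0.0532), while the 4 genes that rose kept theirs.

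**Figure D2:**
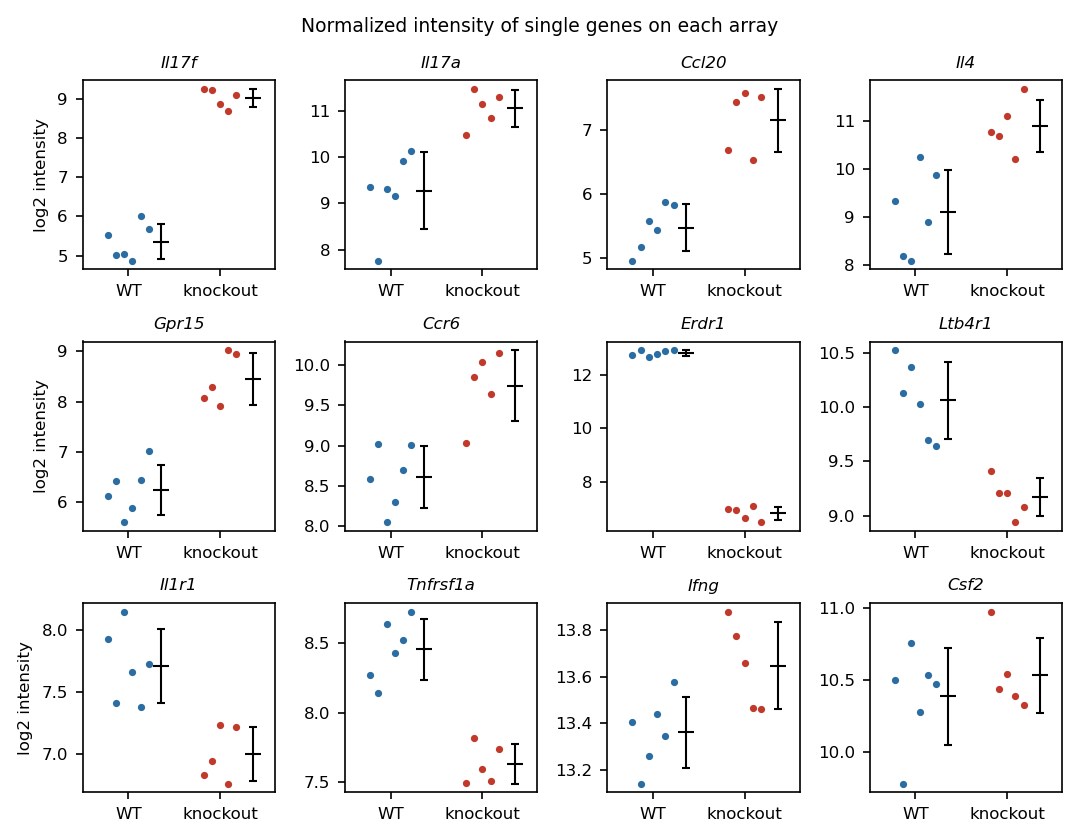
Each panel shows the normalized log2 intensity of 1 gene on the 6 WT arrays (blue) and the 5 knockout arrays (red), with the mean and SD of each genotype in black; the y axes differ and do not start at 0. Il17f and Erdr1 separate the genotypes by several log2 units, while Csf2 (10.39 in WT, 10.53 in knockout cells) overlaps.

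Of the 15 measured genes tied to pathogenic, IL-23-dependent T cells, Il1r1 was the only gene to pass, and it fell. Csf2, the growth factor gene for granulocytes and macrophages, was at 0.15 ± 0.16 (adjusted p = 0.679), Il18r1 at 0.29, and the chemokine gene Ccl3 at 0.70, without passing. Adjusted over the list alone, Il1r1 was again the single gene, and the set test gave an adjusted p of 0.735 (list median 0.00). The type 1 program, with 15 measured genes, had 0 past the threshold, also when adjusted over the list alone. Ifng, its signature cytokine, was at 0.29 ± 0.10 (adjusted p = 0.178), its transcription factor Tbx21 at -0.04 ± 0.09 (adjusted p = 0.867), and Il12rb2 at -0.38. Its median was -0.05 and its mean 0.01, with a set test adjusted p of 0.895.

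Of 8 measured type 2 genes, 2 rose in knockout cells, Il4 and the interleukin 25 receptor gene Il17rb (1.21 ± 0.23, adjusted p = 0.0165), and 7 had positive values, among them Il5 (1.27 ± 0.41, adjusted p = 0.133), Il13 (0.82) and the lineage factor Gata3 (0.37 ± 0.13, adjusted p = 0.167). Adjusted over the list alone, 5 passed, each higher. The set test with a preset correlation gave an adjusted p of 0.0014, but the call was lost with an estimated correlation (adjusted p = 0.524). Of 17 regulatory T cell genes 2 rose, the ecto-nucleotidase gene Nt5e (0.44 ± 0.09) and the integrin gene Itgae (0.60 ± 0.12), and 3 passed when adjusted over the list alone. The list median was 0.31, and it ranged from 0.15 to 0.38 when 1 array was left out. The set test gave a camera adjusted p of 0.0213 (adjusted p = 0.524 with an estimated correlation). This call was lost without WT sample 2 or knockout sample 3 or 5 (adjusted p = 0.0774, 0.0926 and 0.146), and that of Itgae without WT sample 3 or knockout sample 2 (adjusted p = 0.0535 and 0.0555). With equal medians neither Nt5e nor Itgae passed (adjusted p = 0.15 and 0.0574). Myeloid markers had a median of 0.28 in the same comparison.

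Foxp3, the lineage factor of regulatory T cells, differed by probe. Its brightest probe, which stood for the gene in the list, was at 0.03 ± 0.09 (adjusted p = 0.91). Dimmer probes rose by 1.07 ± 0.19 (adjusted p = 0.0129) and 1.34 ± 0.29 (adjusted p = 0.0348), and another was at 1.23 ± 0.34 without passing (adjusted p = 0.0973). Il10 was at 0.55 ± 0.35 (adjusted p = 0.439). The probe at 1.34 missed the threshold in 9 of the 11 fits that left out 1 array (adjusted p up to 0.0784). In the same fits the adjusted p of the probe at 1.23 ran from 0.0177 to 0.194. With the replicate number as a block the probe at 1.23 passed (1.49, adjusted p = 0.0173).

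Among 27 measured cytokine and chemokine genes, 4 rose and 0 fell, namely Il17f, Il17a, Il4 and Ccl20, and 7 passed when adjusted over the list alone. The list median was 0.29 (camera adjusted p = 0.000152, and adjusted p = 0.524 with an estimated correlation). Cytokine receptor genes went both ways: of 24, Tgfbr1 (0.48) and the interleukin 10 receptor gene Il10rb (0.37) rose, while Tnfrsf1a, the tumor necrosis factor receptor gene (-0.82 ± 0.11, adjusted p = 0.00233), Il17re and Il1r1 fell. Adjusted over that list alone, 3 passed as higher and 5 as lower, and its set test gave an adjusted p of 0.417 (median -0.06). Tgfbr1 and Il10rb missed the threshold in 8 and 9 of the 11 fits that left out 1 array (adjusted p up to 0.0786 and 0.123), and with equal medians (adjusted p = 0.116 and 0.13). Of 15 gut homing and adhesion genes, Gpr15, Ccr6 and Itgae rose, and 4 passed when adjusted over the list alone (median 0.19, camera adjusted p = 0.0839). The homing median was 0.02 without WT sample 5, and the list passed without WT sample 1 or 6 or knockout sample 1 (adjusted p = 0.0388, 0.0489 and 0.0268) and with equal medians (adjusted p = 0.0392).

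Of 21 measured heat shock and immediate early genes, 3 rose: Jun, a subunit of the AP-1 transcription factor (0.82 ± 0.15, adjusted p = 0.0143), and the chaperone genes Dnajb1 (0.95 ± 0.18) and Hspa1a (1.09 ± 0.24). Adjusted over the list alone, 6 passed, each higher. The list median was 0.19 (camera adjusted p = 0.00429, and adjusted p = 0.524 with an estimated correlation), and the call was lost without knockout sample 5 (adjusted p = 0.0615), and that of Hspa1a in 8 of the 11 fits that left out 1 array (adjusted p up to 0.0999). With the replicate number as a block, Jun, Dnajb1 and Hspa1a missed the threshold (adjusted p = 0.0637, 0.0829 and 0.113). Interferon response genes had 0 of 18 past the threshold, with Gbp2 at 0.47, Igtp at 0.41 and Ifit3 at 0.71, and 4 passed when adjusted over the list alone. Their median was 0.14 (camera adjusted p = 0.0213, and adjusted p = 0.524 with an estimated correlation), a call lost without WT sample 2 or 4 or knockout sample 3 or 5 (adjusted p up to 0.164).

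Of 32 measured cell cycle genes 25 had negative values, and 0 passed on their own, with the ribonucleotide reductase gene Rrm2 at -0.48 ± 0.12 (adjusted p = 0.076), Ube2c at -0.58 and Kif11 at -0.47. Adjusted over the list alone, 2 passed as lower. The list median was -0.26 (camera adjusted p = 0.000152), and the estimated correlation between its genes was 0.64, with which the call was lost (adjusted p = 0.622). Glycolysis genes, of which 0 of 14 passed, had a median of -0.12 (camera adjusted p = 0.0365, and adjusted p = 0.524 with an estimated correlation), with the glucose transporter gene Slc2a3 at -0.32 and Ldha at -0.19. Oxidative phosphorylation genes, of which 0 of 23 passed, had a median of -0.06 (camera adjusted p = 0.026, and adjusted p = 0.524 with an estimated correlation), with Sdhb at -0.28. The glycolysis call was lost without WT sample 3 or 5 or knockout sample 1, 2, 4 or 5 (adjusted p up to 0.136), and the other without WT sample 3 or knockout sample 3 or 5 (adjusted p up to 0.089).

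The remaining T cell lists did not pass the set test, although the naive and memory list did with the mean of all probes of a gene (adjusted p = 0.0426). The naive and memory program (9 genes, median 0.19) had Id3, an inhibitor of E protein transcription factors, as the single gene that rose (0.75 ± 0.14, adjusted p = 0.0158), a call lost on the authors' values (0.29, adjusted p = 0.0724). In the apoptosis and survival list (17 genes, median 0.03) the death-promoting gene Bcl2l11 fell (-0.41 ± 0.09, adjusted p = 0.0407), a call lost in 9 of the 11 fits that left out 1 array (adjusted p up to 0.112) and with equal medians (adjusted p = 0.295). The follicular helper program (10 genes, median -0.02), inhibitory receptors (9 genes, median -0.02), JAK STAT targets (18 genes, median -0.03) and cholesterol synthesis (16 genes, median -0.09) had 0 genes past the threshold, with Slamf6 at 0.77, Havcr2 at -0.38, Bcl3 at -0.42 and Dhcr7 at -0.35. In the follicular helper list 2 genes passed when adjusted over the list alone. Median, mean and test differed in sign for the IL-17, type 1, follicular helper, JAK STAT and apoptosis lists.

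Markers of T cells and of other cells of the colon were measured alongside. The 13 T cell identity genes had 0 past the threshold (median -0.06), with Thy1 at -0.11, Cd2 at -0.18, Cd4 at -0.22 and Cd247 at -0.44. That list passed as lower on the authors' values (median -0.11, camera adjusted p = 0.00418) and with equal medians (camera adjusted p = 0.0283). Of 14 myeloid markers 13 had positive values and 0 passed, with Lyz1 at 0.44, H2-Aa at 0.29 and Cd74 at 0.23. The median was 0.28 (camera adjusted p = 0.0868, and adjusted p = 0.808 with an estimated correlation), and the list passed without WT sample 2 or 3 (adjusted p = 0.00727 and 0.00824). It also passed with equal medians (adjusted p = 0.0283), the authors' values (0.0478), array weights (0.0388) and the mean of all probes of a gene (0.0415). The medians of the cytokine, type 2, regulatory, stress and interferon lists were also positive. Whether these lists and the myeloid markers rise on the same arrays was not tested. Epithelial markers (9 genes, median -0.04) and CD8, natural killer and innate lymphoid markers (9 genes, median 0.18) had 0 past the threshold, with Lgals4 at 0.11 and Klrd1 at 0.56. When 1 array was left out, these medians ranged from -0.33 to 0.04 and from 0.06 to 0.32. Adjusted over each list alone, 1 epithelial gene passed as higher and 1 as lower, and 1 of the CD8, natural killer and innate lymphoid genes passed as higher. Too few genes were measured for a set test of granulocyte (3 genes), B and plasma cell (2), stromal (3) and erythroid (1) markers. Of these Mmp9 rose (0.50 ± 0.11, adjusted p = 0.0398; lost in 9 of the 11 fits that left out 1 array, with adjusted p up to 0.109), while S100a8 was at -0.79, Xbp1 at -0.04, Pecam1 at -0.13 and Hba-a1 at -0.29.

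**Figure D3:**
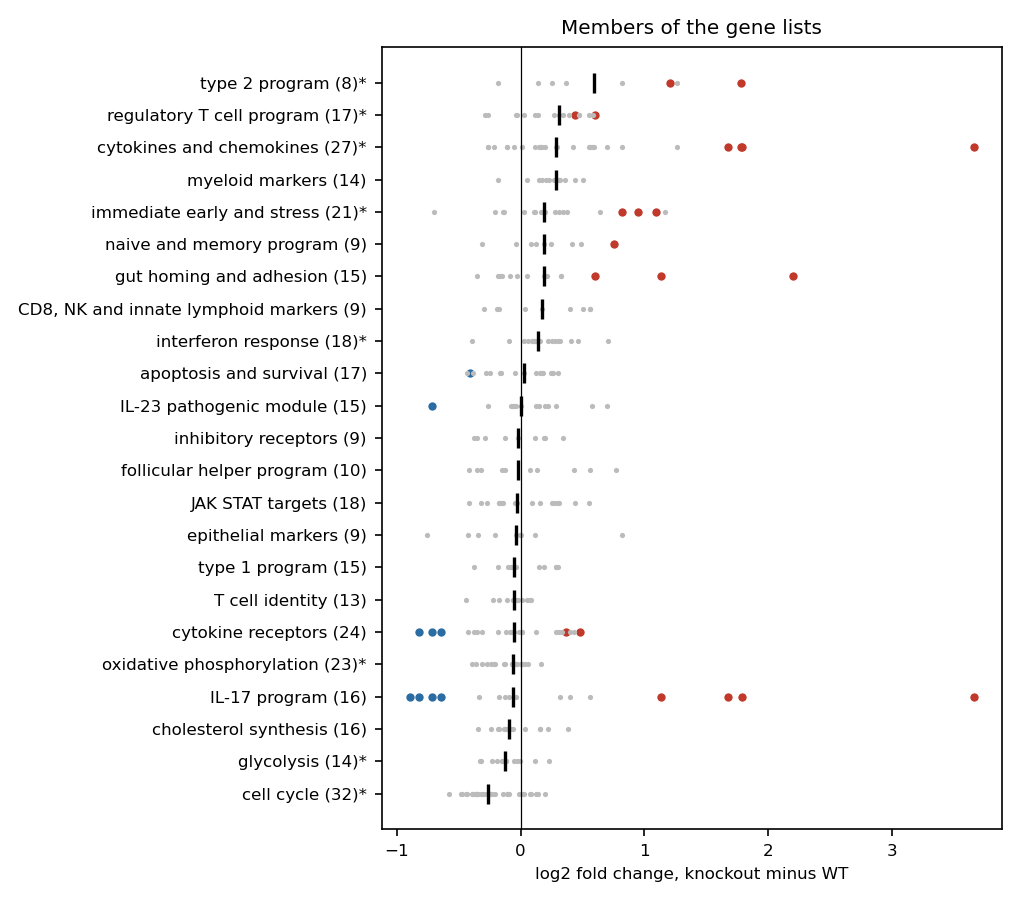
Each row is 1 of the 23 tested gene lists with its number of measured genes in brackets; points are the log2 fold changes, knockout minus WT, of the members (red and blue where adjusted p was under 0.05, grey otherwise), black bars are list medians, and an asterisk marks the 8 lists at camera adjusted p under 0.05 with a preset correlation. The medians run from -0.26 for cell cycle to 0.59 for the type 2 program, and 0 lists passed with an estimated correlation.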

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

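The tests on WT sample 2 and the test of second probes in 4 genes were chosen after the result was seen, and the brightness covariate was added after the data were seen.

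In 17 of 440 groups of values, 1 sample lay far from the others of its genotype, where chance gives about 22. Among knockout samples, sample 1 was low for Gprasp2 (7.33, the others 8.32 to 8.52), for 2 probes of Gprasp1 (9.83 and 8.07) and for Apaf1 (11.37). Knockout sample 5 was high for a Foxp3 probe (9.40, the others 8.51 to 8.65), Gpr83 (6.62) and Gata3 (11.64). Knockout sample 3 was high for Pgk1 (13.10) and low for Dcn (5.10), and knockout sample 4 was low for Socs2 (11.50). Among WT samples, sample 1 was high for Reg3b (11.43, the others 8.51 to 9.58) and an Lgals4 probe (6.92), and sample 2 was low on 2 probes of Havcr2 (9.15 and 8.99). WT sample 3 was high for a Pecam1 probe (8.09), and WT sample 6 was low for Ifit2 (7.51) and high for an Ifng probe (13.59).

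The genes called between genotypes, led by Erdr1, Il17f and Ide, could reflect the missing receptor or DNA that differs between the donors. Of the 20 genes with the largest fold change, 0 lay among the 100 measured genes nearest to Il23r, and the called genes were not enriched there (Fisher exact test, p = 0.704) or near Thy1 (Fisher exact test, p = 0.916). Donors of different sex are argued against by the Y-linked genes, whose 95% intervals of log2 fold change stayed within 0.551 of 0. Open are DNA around Ptprc (Fisher exact test, p = 0.226, 4 called genes near it) and a sequence variant under a single probe, since in 80% of the 5 genes with several tested probes another probe moved less than 50% as far or the other way, Ide among them, while 15 of the 20 genes had 1 tested probe. Erdr1, Cdk5rap1, Gpr15 and Igf2bp3, 4 of these 5 genes, had another probe past the threshold in the same direction (Erdr1 -5.98 and -5.09, Cdk5rap1 2.25 and 2.23). A test of these 4 alone decides nothing, since they were picked for it, but the count covers all 5 genes. It argues against a variant under 1 probe alone in these 4, unless their probes share sequence, which was not checked. Gpr15 entered the 80% at 49.6%, close to the 50% limit. The variant stays open for Ide and the 15 genes with 1 tested probe. DNA that differs elsewhere in the genome also stays open, since only the surroundings of Il23r, Thy1 and Ptprc were tested.

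Il17a, Il17f, Ccl20, Gpr15 and a Foxp3 probe were higher in knockout cells, which may follow from the missing receptor, a hypothesis found and tested on the same data. A difference in array brightness is argued against, since 5 of the 5 genes stayed past the threshold with brightness as a covariate (Il17a 1.94 ± 0.30, SE). Each of the 320 called probes stayed past it as well, so this result is not particular to the 5 genes. For cells of another type in the sorted knockout samples, the highest median among their marker lists was 0.283, for myeloid markers. It ranged from 0.14 to 0.43 when 1 array was left out. Myeloid cells are argued against as the source of the 5 genes. On WT samples 2 and 3 the most abundant myeloid markers, Lyz1, H2-Aa and Cd74, lay within or above their knockout range. Lyz1 was at 11.96 and 11.72 there, against 10.80 to 11.77 on knockout arrays. Each of the 5 genes was lower on these WT samples than on every knockout array (Il17f 5.01 and 5.04, knockout 8.68 to 9.24). Other cell types cannot be told apart from a change within T cells.

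On the first principal component (28.4% of the variance) WT sample 2 lay nearer to the knockout arrays than other WT arrays did. It was at 11.3, against -32.0 to -0.434 for the other WT and 4.25 to 25.9 for knockout samples. On the second (20.7%) it was at 20.2, away from the knockout samples at -21.5 to 12.6. The first component also fell with the sample number among knockout samples, from 25.9 in sample 1 to 4.25 in sample 5. Whether a factor that follows the sample number placed WT sample 2 was not tested. A wrong label is argued against by its median place of 0.00603 over the 20 largest genes, on a scale from 0 (WT mean) to 1 (knockout mean), and an admixture of knockout cells by a place of -0.00853 over 5 genes at least 4-fold higher in knockout cells. Over all called probes its place was 0.473. Array brightness stays open as a possible explanation: with it as a covariate, leaving out this sample raised the count of called probes by a factor of 1.19, against 320 to 513 without it. No biological explanation was tested for this sample.

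The count of called probes was compared with that of other splits of the samples into 6 and 5. Of 100 splits, the real one included, 2 gave as many as its 320. This argues against chance as the source of the count but does not exclude it, since another split gave more. The highest of the other splits gave 449 and set knockout samples with WT sample 2 against the remaining WT samples, and the next gave 24.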

How the results depend on the processing

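The brightness covariate and replicates 1 to 5 alone were chosen after the data were seen. No called value among the 218 reported probes and 23 gene lists reversed, while 53 probe values and 26 list values that did not pass changed sign: of 4486 probe values 4155 kept their side of the threshold, 243 lost it and 88 gained it, and of 527 list values 485 kept it, 28 lost it and 14 gained it. Against 320 called probes (210 higher, 110 lower), the count was 210 (133 higher, 77 lower) without a detection filter, where more probes were tested, 649 (403 and 246) at adjusted p under 0.1, 190 (123 and 67) with a fold minimum, and 512 (321 and 191) with the brightness covariate. Equal medians gave 58 lower and array weights 168 lower probes. Of 8 called gene lists, 5 remained under the strict filter, where the type 2 list had too few genes to test, and 0 with an estimated correlation; where construction does not show it, the cause was not tested. Leaving out 1 array gave 159 to 513 called probes (95 to 326 higher, 63 to 187 lower) and 3 to 9 lists. With the replicate block, 264 probes were called (161 higher, 103 lower), 187 of them shared. Of the reported probes, 21 lost their call with the block and 5 gained one. Besides Jun, Dnajb1 and Hspa1a, the calls lost include those of Il4, Id3, Znhit6 and Tgfbr1 (adjusted p = 0.0588, 0.0582, 0.0588 and 0.0577). Same-numbered samples correlated at -0.01 to 0.26, over 0.1 in 3 of 5 pairs. Only 3 of the 5 WT samples with a partner and 1 of the 5 knockout samples correlated best with their own number. Neighbouring numbers still shared structure. WT sample 6 correlated at 0.32 and 0.29 with knockout samples 4 and 5, and at -0.42 with knockout sample 1. In both genotypes samples 1 and 2 had the highest median intensities (165.3 and 156.7 in WT, 176.7 and 164 in knockout). A factor that follows the sample number was not a term of the main test. A slide block was not run, since no slides are named in the sources used here. Signal over background limits Il23r and Il22.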

Other observations

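The genes in the next paragraph were chosen after their values were seen, so their p-values rank them and do not test them as a group.

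Knockout cells held more transcript of Arrdc4 (1.26 ± 0.13, SE, adjusted p = 0.000225) and Txnip (0.67 ± 0.08, adjusted p = 0.00078), 2 related arrestin family genes that restrain glucose uptake. Gprasp1, a relative of Gprasp2, rose by 1.31 and 1.10 on 2 probes, with another at 0.17 that did not pass. The interferon-inducible gene Ifitm1 rose by 1.00, 0.94 and 0.88 on 3 of 5 probes, and Ifit1bl1 rose by 0.89 and Trim30d by 0.65. Trgv4, a γ chain variable segment of the T cell receptor, rose by 0.80. Smox, the spermine oxidase gene, fell on each of its 5 probes (-1.01 to -0.56). The glutathione transferase gene Gstt3 (-0.90), the quinone reductase gene Nqo2 (-0.53 on 1 of 3 probes), the sulfiredoxin gene Srxn1 (-0.47 on 1 of 2 probes), S100a4 (-0.91) and Lgals1 (-0.42) also fell. Nqo2 and Lgals1 each missed the threshold in 8 of the 11 fits that left out 1 array, 2 of the Smox probes in 7 and 9 (adjusted p up to 0.0977), and Trim30d in 4. With equal medians Srxn1, Nqo2 and Lgals1 did not pass (adjusted p = 0.155, 0.241 and 0.148).

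The probes of Wdfy1 went in opposite directions, 0.94 ± 0.10 on 1 and -0.84 ± 0.13 on the other (adjusted p = 0.000326 and 0.0053).

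Called genes were direct neighbours in the order of the measured genes on their chromosome in 12 pairs, against 5.36 by chance (permutation p = 0.0083). Among the pairs were Il17a with Il17f, Gstt3 with Gstt1 and Mid1 with Erdr1. Unmeasured genes can lie between the members of a pair, and Gstt3 was paired with both Ddt and Gstt1. The permutation shuffled the calls freely over the genes, so it does not allow for related neighbours that change together. Whether DNA that differs between the donors gave rise to such pairs was not tested.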
